A study of Mus musculus with 12 samples.

How the data were processed

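RNA was measured in 12 libraries from the extensor digitorum longus of C57BL/6 mice, with 3 libraries each from single myofibers, pools of 5 myofibers, pools of 20 myofibers and whole muscle. Per the labels the molecule was total RNA, single myofibers were lysed directly in lysis buffer, whole muscle RNA was extracted with Trizol, and all libraries were made with the SMART-Seq HT kit. The deposited values are raw whole-number read counts per Ensembl gene, with no normalization, and the authors name HISAT2, SAMtools and featureCounts on GRCm38 (mm10), without versions, strand or multi-mapping settings or annotation release. Of the 55573 gene identifiers in the file, 55480 matched the GENCODE vM21 annotation of GRCm38, from which symbols, gene types, coordinates and exon lengths were taken, and the 93 others kept their identifier as name. Groups and replicate numbers were taken from the labels, which name no batch, animal or sequencing date. Totals ranged from 4702823 to 27787120 counted reads per library. Libraries of the same group were checked for duplicates, and none were near copies of each other.

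Differential expression was tested with edgeR 4.0.16 in R 4.3.3, with TMM factors, filterByExpr on the groups in the fit, glmQLFit and glmQLFTest, and Benjamini-Hochberg adjusted p under 0.05, with no fold minimum. Each of the 6 pairs of groups was fitted on its own 6 libraries, so that each comparison estimated its own spread. The comparison of isolated myofibers with whole muscle was fitted on all 12 libraries and 4 groups, as the mean of the 3 fiber groups minus whole muscle. CPM are counts divided by the TMM-scaled total. A fold against a group with 0 reads is a lower bound computed with 3 counts over the group. For 1 to 3 counts the ratio of pooled reads is given with its counting interval at the 95% level.

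A set of 21 gene lists was written before the data were examined, 11 for pathways and 10 for markers of cell types. The pathway lists were fast sarcomere and calcium handling, slow sarcomere, glycolysis and glycogen, fatty acid oxidation and uptake, nuclear-encoded respiratory chain, mitochondrially encoded mRNA, cytosolic ribosomal protein, immediate early, heat shock and metal stress, denervation and atrophy, and neuromuscular junction. The marker lists were endothelial, pericyte and smooth muscle, fibroblast, tendon, macrophage and antigen presentation, lymphocyte and granulocyte, erythroid, Schwann cell and nerve, adipocyte, and satellite cell. They were tested with camera of limma 3.58.1 on voom values with a preset inter-gene correlation of 0.01, beside it with an estimated correlation, and with fry, with adjustment over the lists of a comparison. Calls of members are counted over all genes tested and adjusted over the list alone.

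Genes to be named were fixed by a rule before the data were examined. For isolated myofibers against whole muscle and for single fibers against pools of 20 these were the 8 largest log2 fold changes in each direction, and for the other comparisons the 4 largest. They were taken among genes with adjusted p under 0.05, a mean of 10 CPM or more and no overlap between the sides, leaving out predicted genes, pseudogenes and list members. For each list the rule took the 3 members with the highest mean CPM and the 2 called members with the largest change in isolated fibers, and it always took Myh1, Myh2, Myh4 and Myh7.

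Background reads were measured on 1501 protein-coding olfactory, vomeronasal and taste receptor genes. A gene was said to lie within the background density when its reads per kilobase of exon in the group lay at or under the 99th percentile of these genes. To find shared sequence, a fixed sample of 1 in 8 of the 50-base windows in the transcripts of each list gene was taken. These were looked up, on either strand, in the annotated transcripts of all other genes. A window called shared with another locus was found in a transcript of another annotated gene. Sequence outside annotated transcripts was not searched. The detected genes per library were counted after thinning all libraries to the smallest total with a fixed seed (20), as genes with 1 or more reads. The spread between replicates was, after the same thinning, the median over genes with a mean of 10 CPM or more over the 12 libraries of the SD of log2 CPM (offset 0.5). Myosin shares carry Clopper-Pearson 95% intervals. Group means of single values were compared by exact two-sided permutation tests, for which 3 against 3 libraries cannot give p under 0.1. Calls shared between the 3 comparisons with whole muscle were set beside the number expected of independent calls and beside 20 simulations of unchanged groups.

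The fits were tested on simulated data with the library sizes and gene levels of each comparison, in which 200 genes were changed, the first 100 by 2-fold and the others by 4-fold. At a dispersion of 0.01 all changed genes were called, in the right direction, and at most 0.139% of unchanged genes were called. At the dispersions estimated in these libraries the share of 4-fold changes called was 21% for isolated fibers, 6% for single fibers and 54% for pools of 20 against whole muscle, and 0% in the other 4 comparisons.

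Alternatives fixed before the data were examined were RLE and upper-quartile size factors, the Wald test of DESeq2 1.42.0, limma voom with sample quality weights, no low-count filter, a mean of 5 CPM or more, a fold minimum of 2, counts thinned to the smallest library, the replicate number as a block, all 12 libraries in the fit or a model of 2 groups, and leaving out each library in turn. For detected genes, spread, myosin shares and overlaps other minimums, no thinning, a denominator of 9 sarcomeric myosin genes and DESeq2 were tried. Chosen after seeing the data were the subtraction of expected background reads (receptor-family read density times exon length), a fit of protein-coding genes only, and fits without the 5 libraries in which over 50% of the receptor-family genes had a read. Splits of the libraries into other groups of the same sizes were fitted in the same way, 10 for each pair of groups and 100 drawn for isolated fibers. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. No column of the count table was left out.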

Results

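RNA sequencing measured gene expression in the extensor digitorum longus, a fast hindlimb muscle, of C57BL/6 mice. The 12 libraries fell into 4 groups of 3: single myofibers, pools of 5 myofibers, pools of 20 myofibers and whole muscle. All were made with SMART-Seq HT, a kit that makes full-length cDNA from very little RNA. Per the labels, single myofibers were lysed directly in the kit's lysis buffer and whole muscle RNA was extracted with Trizol; the labels make no separate statement for the pools. For single fibers, isolation and the way the RNA was obtained therefore changed together against whole muscle. The totals of counted reads were 19001774, 27787120 and 12685900 in single fibers 1 to 3, and 20880728, 8434050 and 24719718 in the pools of 5. They were 8524467, 4702823 and 15345348 in the pools of 20 and 8088137, 19807973 and 20895762 in whole muscle. The labels do not say whether replicates came from separate animals, so the p-values measure the spread between these libraries. Apart from bootstrap intervals, the intervals and the limits given for counts of 0 cover counting error only. Folds in isolated fibers are those of the mean of the 3 fiber groups on the log scale, and CPM are counts set to a common total with factors by the trimmed mean of M-values (TMM). A number in parentheses directly after a list's count is that count adjusted over the list alone.

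Reads on genes that muscle is not known to express differed between the groups. Of 1501 olfactory, vomeronasal and taste receptor genes, which sensory neurons and taste cells express, 2.20%, 4.80% and 3.06% had a read in the 3 whole muscle libraries. In single fibers the shares were 26.5%, 4.73% and 9.79%, in pools of 5 fibers 58.0%, 68.8% and 4.397%, and in pools of 20 fibers 78.6%, 97.3% and 95.4%. Reads on these genes reached 8905 RPM in 20-fiber pool 2, against 21.9 RPM in the whole muscle library with most. Unlike CPM, RPM are set to a common total by each library's own count of reads, without TMM factors. The predicted gene Gm10800 took 20.9% of the reads of 20-fiber pool 2 (Clopper-Pearson 95% interval 20.85% to 20.93%), and 0.000408% of those of whole muscle 1 (0.000281% to 0.000573%). The mitochondrial ribosomal RNAs took 38.3% of the reads of 5-fiber pool 1 (38.29% to 38.33%) and 34.2% of those of pool 2 (34.13% to 34.19%), against 2.39% (2.38% to 2.39%) in pool 3 and a mean of 2.58% (SD 0.213, n = 3) in whole muscle. Below, a gene whose read density lay at or under the 99th percentile of the receptor-family genes is said to lie within the background density.

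**Figure D1:**
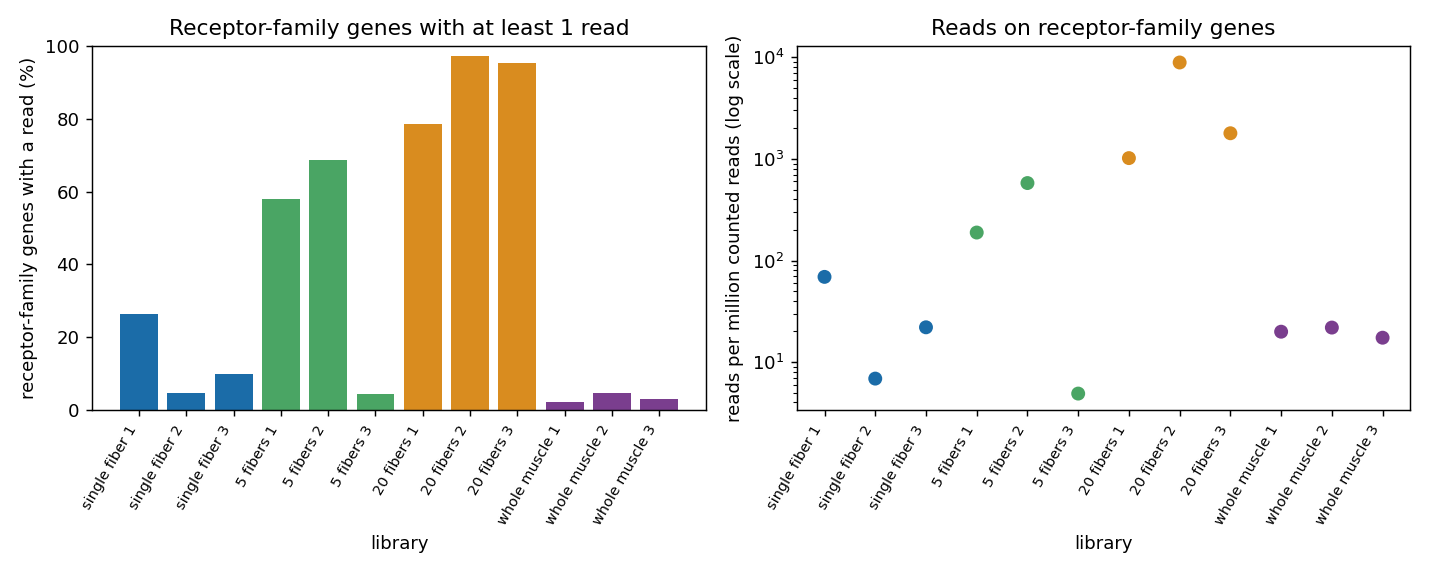
The left panel gives, for each of the 12 libraries, the percentage of the 1501 receptor-family genes with at least 1 read, and the right panel the RPM of these genes, on a log scale. The 3 pools of 20 fibers lie highest in both panels, with 78.6%, 97.3% and 95.4% of the genes read, while the whole muscle libraries stay at or below 4.80%.

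The comparison of all isolated myofibers with whole muscle asks what distinguishes the RNA of dissected fibers from that of the tissue they come from. Immediate early genes, the transcription factors and regulators that cells switch on within minutes of a stimulus, were higher in isolated fibers. Of 31 tested, 24 rose, 0 fell, and the median log2 fold change was 2.89 (camera adjusted p = 3.18e-12). With an estimated correlation the adjusted p = 0.143, and adjusted over the list alone 29 rose and 1 fell. Fosb (ENSMUSG00000003545, GRCm38 chromosome 7, 19302696 to 19310051, minus strand) was at 98.8 ± 88.5 CPM (SD, n = 9) against 0.169 ± 0.0856 (n = 3), a log2 fold change of 8.66 (SE 0.90, adjusted p = 6.92e-06). Egr1 (ENSMUSG00000038418, chromosome 18, 34859823 to 34864984, plus strand) was at 1009 ± 602 CPM against 12.5 ± 2.44, a 73.2-fold difference (adjusted p = 2.85e-04). Fos was 90.7-fold higher (adjusted p = 3.77e-04), Btg2 24.9-fold higher (adjusted p = 0.00130), and Fosl1, with 0 reads in whole muscle, at least 46.1-fold higher. The number of immediate early genes that rose was 15 without whole muscle 1 and 15 without whole muscle 2, and the Fosl1 call was lost without 20-fiber pool 2.

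Heat shock and metal stress genes rose in isolated fibers, 8 of 17 with 0 lower (11 adjusted over the list alone) and a median of 2.14 (camera adjusted p = 7.58e-05; adjusted p = 0.356 with an estimated correlation). The metal-binding metallothioneins Mt2 and Mt1 rose 112-fold and 33.3-fold, and the inducible chaperone Hspa1a 97.8-fold (adjusted p = 0.00180), with 67.0% of its sampled 50-base windows shared with another locus. The small heat shock protein genes Hspb8 (2.14, adjusted p = 0.0795) and Cryab (1.58, adjusted p = 0.147) did not pass. Of 20 denervation and atrophy genes, 5 rose and 3 fell (10 and 4 adjusted over the list alone), with a median of 1.16 (camera adjusted p = 0.287; adjusted p = 0.708 with an estimated correlation). Ankrd1, a mechanically responsive ankyrin-repeat gene (ENSMUSG00000024803, chromosome 19, 36111961 to 36120099, minus strand), was at 1809.8 ± 2845 CPM against 7.24 ± 0.922, a log2 fold change of 6.70 (SE 1.28, adjusted p = 0.00218). The muscle ubiquitin ligase Trim63 (1.73, adjusted p = 0.114) and the perinatal myosin Myh8 (-0.20, adjusted p = 0.934) did not pass. Of the denervation and atrophy genes, 8 rose without single fiber 2, while without whole muscle 1, 2 or 3 only 2 rose and 1 fell each time. None of 12 neuromuscular junction genes passed, with a median of 0.77 (camera adjusted p = 0.287; adjusted p = 0.708 with an estimated correlation), and 5 rose without 20-fiber pool 2. Chrna1 and Chrnb1, receptor subunits, were at 0.67 (adjusted p = 0.430) and 1.06 (adjusted p = 0.125).

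Of 12 slow sarcomere genes, 8 fell and 0 rose (10 lower adjusted over the list alone), with a median of -3.99 (camera adjusted p = 4.21e-09; adjusted p = 0.0359 with an estimated correlation). Tnnc1, the slow and cardiac troponin C (ENSMUSG00000091898, chromosome 14, 31208312 to 31211729, plus strand), was at 0.398 ± 0.619 CPM (n = 9) against 95.5 ± 32.1 (n = 3), a log2 fold change of -8.02 (SE 0.67, adjusted p = 5.32e-07). The slow myosin genes Myh7 and Myl3 fell by 7.04 and 6.45, and the tropomyosin Tpm3 by 2.97. Of 30 fast sarcomere and calcium handling genes, 1 rose (Ryr1, the calcium release channel, 2.61, adjusted p = 0.0244) and 1 fell (Myh2, the type IIa myosin, -1.81, adjusted p = 0.0339). Their median was 0.39, while the camera test, which sets a list against all other genes, pointed down (adjusted p = 0.496; adjusted p = 0.880 with an estimated correlation), and 0 passed adjusted over the list alone. The Ryr1 call was lost without single fiber 1 or 3, 5-fiber pool 1, 20-fiber pool 1 or 3, or any whole muscle library. That of Myh2 was lost without single fiber 3, 5-fiber pool 1, 20-fiber pool 1 or any whole muscle library. Without the 5 libraries in which over 50% of the receptor-family genes had a read, a choice made after seeing the data, 11 fast sarcomere genes rose.

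Ribosomal protein genes rose, 13 of 58 with 0 lower (23 adjusted over the list alone), with a median of 1.38 (camera adjusted p = 8.04e-06; adjusted p = 0.581 with an estimated correlation), as in Rps28 (2.75, adjusted p = 0.00893) and Rps15 (2.35, adjusted p = 0.0206). Both calls were lost without any whole muscle library (0.0740 to 0.160), and that of Rps15 also without single fiber 1, 5-fiber pool 1 or 20-fiber pool 1 (0.0502 to 0.0576). Their list's number was 40 without 20-fiber pool 2, 1 and 3 without 20-fiber pools 1 and 3, 2 and 6 without single fibers 1 and 3, 2 and 8 without 5-fiber pools 1 and 2, and 0 without any one whole muscle library. Of 13 mitochondrially encoded mRNAs 4 rose (4 adjusted over the list alone), with a median of 2.59 (camera adjusted p = 9.93e-04; adjusted p = 0.436 with an estimated correlation), among them mt-Nd6 (3.13, adjusted p = 0.0364; 0.0693 to 0.226 without each of 10 libraries, all but 5-fiber pool 3 and 20-fiber pool 2). Another, mt-Co2, rose by 3.12 (adjusted p = 0.0167), with 100% of its windows shared with another locus, and lost its call without any whole muscle library (0.0902 to 0.0954). For these mRNAs the number was 7 without 20-fiber pool 2, 2 without pool 1 or 3, and 0 without any one whole muscle library. Of 20 fatty acid oxidation and uptake genes, 6 fell (8 adjusted over the list alone), with a median of -1.27 (camera adjusted p = 1.71e-05; adjusted p = 0.387 with an estimated correlation). The fatty acid transporter Cd36 fell by 2.10, Pdk4, a kinase that holds back pyruvate oxidation, by 2.06, and the oxidation enzyme Acadvl by 3.90. The number of fatty acid genes that fell was 12 without single fiber 2, 13 without 5-fiber pool 3, and 3 and 2 without whole muscle 1 and 2, where Cd36 (0.0569 and 0.0582) and, without whole muscle 2, Pdk4 (0.0701) did not pass. Neither the 20 glycolysis and glycogen genes nor the 36 nuclear-encoded respiratory chain genes held a call. Glycolysis genes had a median of 0.09 (camera direction down, adjusted p = 0.287; adjusted p = 0.824 with an estimated correlation), with Aldoa at 0.71 (adjusted p = 0.779). Respiratory chain genes had a median of -0.16 and a mean of 0.05 (camera adjusted p = 0.137; adjusted p = 0.824 with an estimated correlation), with Cox8b at 2.03 (adjusted p = 0.0866). Upper-quartile scaling turned that median to 0.08, and 3 of these genes rose without 20-fiber pool 2.

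Markers of fibroblasts, adipocytes, endothelium, macrophages and blood were lower in isolated fibers. All 16 fibroblast markers fell (16 adjusted over the list alone), with a median of -4.21 (camera adjusted p = 3.08e-13; adjusted p = 0.143 with an estimated correlation). Col3a1, a fibrillar collagen (ENSMUSG00000026043, chromosome 1, 45311538 to 45349706, plus strand), was at 57.9 ± 56.4 CPM against 1306 ± 31.9, a log2 fold change of -4.59 (SE 0.74, adjusted p = 5.08e-04). All 8 adipocyte markers fell (8 adjusted over the list alone), with a median of -7.48, or -7.33 with members at 0 set to their bounds (camera adjusted p = 7.88e-14; adjusted p = 0.0516 with an estimated correlation). Cfd, the adipokine adipsin, fell by 12.27 and the adipokine Adipoq by 8.65. Of 16 endothelial markers 15 fell (15), with a median of -2.73 (camera adjusted p = 3.82e-10; adjusted p = 0.192 with an estimated correlation), Fabp4 being 50.9-fold lower. Macrophage and antigen presentation markers fell in 13 of 16 cases (13, and 1 higher, adjusted over the list alone), with a median of -4.60 (camera adjusted p = 1.34e-13; adjusted p = 0.0547 with an estimated correlation). The lysozyme Lyz2 was 125-fold and the class II chaperone Cd74 91.2-fold lower, while the lysosomal gene Cd68 stood at 1.79 (adjusted p = 0.132). Erythroid genes fell in 6 of 7 cases (6), with a median of -4.60 (camera adjusted p = 4.07e-07; adjusted p = 0.0547 with an estimated correlation). The globin Hbb-bs, with 57.6% of its windows shared with another locus, was 38.4-fold lower.

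Schwann cell and nerve genes fell in 7 of 11 cases (8 adjusted over the list alone), with a median of -2.99 (camera adjusted p = 1.96e-09; adjusted p = 0.0465 with an estimated correlation). Of 8 tendon markers 7 fell (7 adjusted over the list alone), with a median of -3.19 (camera adjusted p = 4.21e-09; adjusted p = 0.0516 with an estimated correlation), Tnmd being at least 97.8-fold lower. Pericyte and smooth muscle markers fell in 7 of 11 cases (9), with a median of -2.86 (camera adjusted p = 6.01e-06; adjusted p = 0.143 with an estimated correlation). Rgs5 fell by 3.67 and Acta2 by 3.85. Here too single fibers held most of the falls: 9 pericyte markers fell in them, 1 in pools of 5 and 2 in pools of 20. The potassium channel regulator Abcc9, which muscle fibers also express, stood at 0.67 (adjusted p = 0.394). Of 10 lymphocyte and granulocyte markers, S100a8 (at least 4.49-fold lower) and S100a9 (at least 6.60-fold lower) fell, and the list had a median of -0.76, or -0.41 with bounds (camera adjusted p = 0.0960; adjusted p = 0.394 with an estimated correlation). This count was 1 without single fiber 1 or 20-fiber pool 3 and 0 without 5-fiber pool 1, 20-fiber pool 1 or 2, or any whole muscle library. Adjusted over the list alone, 1 of these rose and 2 fell. Of 10 satellite cell genes, 1 rose and 2 fell (2 and 3 adjusted over the list alone), with a median of -0.56 (camera adjusted p = 0.0461; adjusted p = 0.218 with an estimated correlation). Myod1, the myogenic transcription factor, rose by 2.91 (adjusted p = 0.0264), a call lost without any whole muscle library (adjusted p = 0.0853 to 0.126), and Heyl, a Notch target, fell by 2.58 (adjusted p = 0.00822).

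**Figure D2:**
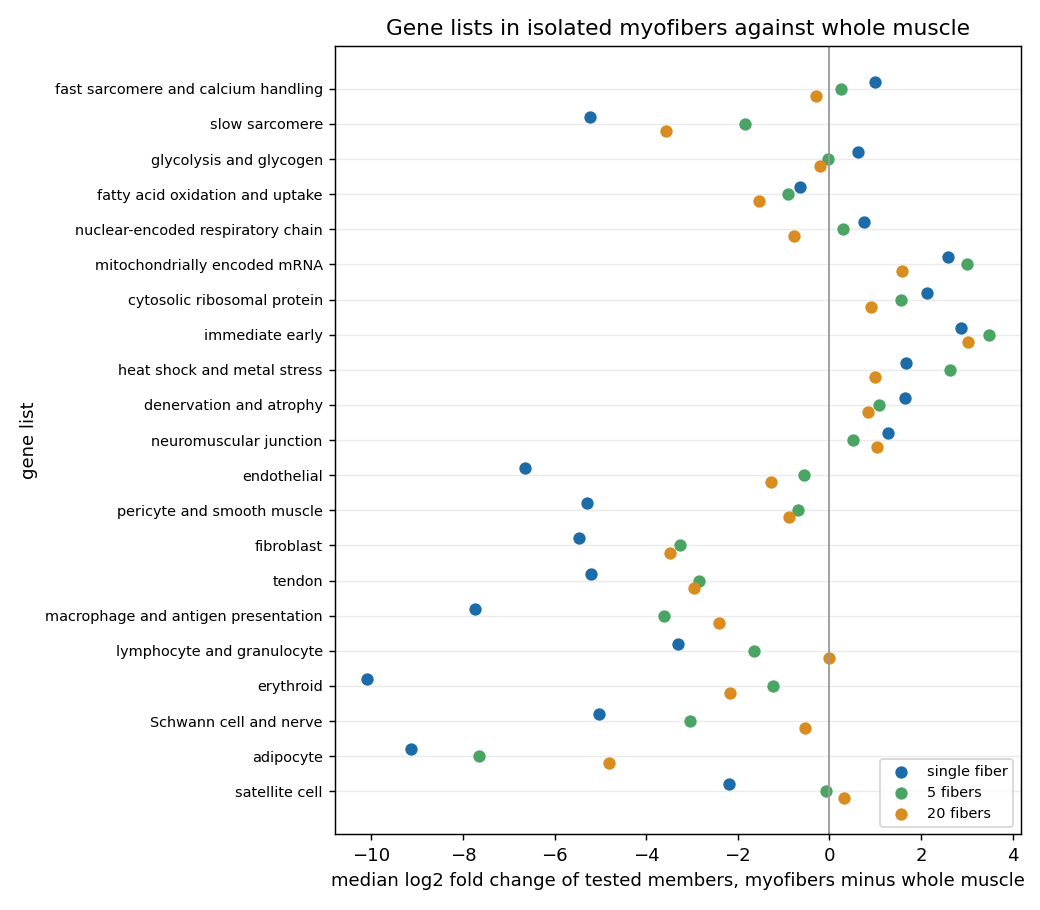
Each point is the median log2 fold change of the tested members of 1 of the 21 lists in single fibers, pools of 5 or pools of 20 against whole muscle, with members at 0 in a group set to their bound. The immediate early list lies at 2.88, 3.49 and 3.04, the adipocyte list at -9.14, -7.64 and -4.80, and the endothelial list at -6.65, -0.56 and -1.27.

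Outside the lists, the genes with the largest rises in isolated fibers included Eid3, Cxcl1, Per2, Midn, Rrad, Ddit3 and mt-Tp. Eid3 (ENSMUSG00000109864, chromosome 10, 82866626 to 82867930, plus strand) was at 22.8 ± 36.9 CPM (n = 9) against 0.0893 ± 0.125 (n = 3), a log2 fold change of 7.78 (SE 1.30, adjusted p = 7.10e-04). The chemokine Cxcl1 rose 66.2-fold, the clock gene Per2 53.3-fold, the small GTPase Rrad 45.9-fold and Ddit3, the stress-response factor CHOP, 38.4-fold. The largest falls were those of Retnla, Hp, Ucp1, Mfap4, Igfbp7, Cyp2e1, Scd1 and Aplnr. Retnla, a secreted resistin-like protein (ENSMUSG00000061100, chromosome 16, 48842551 to 48844461, plus strand), was at 0.415 ± 0.736 CPM against 63.8 ± 15.8, a log2 fold change of -8.15 (SE 0.66, adjusted p = 3.40e-07). Hp, haptoglobin, was 263-fold lower, the lipid desaturase Scd1 81.5-fold, and the brown fat gene Ucp1 at least 92.3-fold.

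In all, edgeR called 3370 of 22110 genes in this comparison, 1650 higher and 1720 lower in isolated fibers, and 7394 had an unadjusted p under 0.05. Of the 1650 higher genes 720 lay within the background density of the fiber libraries and 930 above it. The groups did not overlap in 1754 of the called genes, and 900 of the called genes had a group at 0. TMM put the median of all genes at 0.40, relative log expression (RLE) factors at 0.56 and upper-quartile factors at 0.69. With upper-quartile factors 2119 genes were higher and 1136 lower, so 65.1% of the called genes were higher, against 49.0% with TMM. The count was 5073 without single fiber 2, 7271 without 5-fiber pool 3, 2165 without 20-fiber pool 1, and 1440, 1199 and 1193 without whole muscle 1, 2 and 3. In a model of 2 groups the differences between single fibers, pools of 5 and pools of 20 count as spread among the 9 fiber libraries. It called 596 genes, and 0 of the 16 endothelial markers.

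In single fibers against whole muscle, which compares a lone fiber with its tissue, genes of protein synthesis and stress and part of the fast sarcomere genes rose. Slow sarcomere genes and markers of vessels, connective tissue, blood and fat fell. Of 57 ribosomal protein genes 55 rose (56 adjusted over the list alone), with a median of 2.13 (camera adjusted p = 1.70e-28; adjusted p = 0.170 with an estimated correlation). Rps28 rose by 3.09 (SE 0.28) and Rplp0 by 1.69. Immediate early genes rose in 25 of 30 cases and fell in 1 (26 and 1), with a median of 2.88 (camera adjusted p = 2.82e-10; adjusted p = 0.0969 with an estimated correlation). Btg2 was at 1450.7 ± 460.3 CPM (n = 3), 5.85 log2 units above whole muscle, and Egr1 at 6.75. Of the 17 stress genes 14 rose (14), with a median of 1.68 (camera adjusted p = 5.78e-07; adjusted p = 0.0775 with an estimated correlation), Mt1 by 6.66, Hspb8 by 3.98 and Cryab by 2.93. Ankrd1 rose by 9.23 (SE 1.37, adjusted p = 0.00328) to 4404 ± 3882 CPM, and the denervation and atrophy list gave 12 higher and 3 lower (13 and 3), with a median of 1.66 (camera adjusted p = 0.01002; adjusted p = 0.322 with an estimated correlation). The largest rises outside the lists were Rrad (7.41, SE 1.45, adjusted p = 0.00843), the transcription factor Sox9 (6.91), the sphingomyelin synthase Sgms2 (6.90) and the phosphatase Dusp2 (6.90).

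Fast sarcomere genes, mitochondrial mRNAs and junction genes were among the other lists with genes that rose in single fibers. Of 30 fast sarcomere genes 15 rose and 1, Myh2, fell (16 and 1 adjusted over the list alone), with a median of 1.00 (camera adjusted p = 7.55e-08; adjusted p = 0.200 with an estimated correlation). Among them were Myl1 (1.69), Tnnt3 (1.63) and Acta1 (1.48). Glycolysis genes gave 6 higher and 1 lower (7 and 1), with a median of 0.62 (camera adjusted p = 5.54e-05; adjusted p = 0.251 with an estimated correlation), and Pgam2 rose by 2.03. Respiratory chain genes gave 7 higher and 1 lower of 36 (6 and 1), with a median of 0.76 (camera adjusted p = 0.00169; adjusted p = 0.545 with an estimated correlation), and Cox8b rose by 2.23. Without single fiber 2 the respiratory chain median was 0.08, with 7 higher and 10 lower. Of the 13 mitochondrial mRNAs 10 rose (11), with a median of 2.60 (camera adjusted p = 6.23e-07; adjusted p = 0.216 with an estimated correlation). Of 12 neuromuscular junction genes 7 rose (9), with a median of 1.28 (camera adjusted p = 3.22e-04; adjusted p = 0.0949 with an estimated correlation), Chrna1 by 1.90 and Chrnb1 by 1.29. Fatty acid genes fell in 6 of 19 cases (6), with a median of -0.64 (camera adjusted p = 0.0107; adjusted p = 0.544 with an estimated correlation), and 17 fell without single fiber 2. Slow sarcomere genes fell in 10 of 12 cases (11), with a median of -5.24 (camera adjusted p = 1.57e-06; adjusted p = 0.114 with an estimated correlation), Tnnc1 by 8.92.

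All 16 endothelial markers fell in single fibers (16), with a median of -6.65 (camera adjusted p = 2.10e-10; adjusted p = 0.114 with an estimated correlation). All 16 fibroblast markers fell (16), with a median of -5.47 (camera adjusted p = 6.89e-08; adjusted p = 0.216 with an estimated correlation), all 8 adipocyte markers (8), with a median of -9.94, or -9.14 with bounds (adjusted p = 0.114 with an estimated correlation), and all 7 erythroid genes (7), with a median of -10.11 (adjusted p = 0.0775 with an estimated correlation). Fabp4 held 6 reads over the 3 single fibers against 47719 over whole muscle, and Gpihbp1, an endothelial lipase carrier, 0 reads, at least 1009.8-fold lower. The globin Hbb-bs held 3 reads against 30188, a log2 ratio of -12.47 (counting interval -14.75 to -10.93), and Cfd 1 read against 55580, a log2 ratio of -14.94 (-20.24 to -12.46). Outside the lists the largest falls were those of the vessel genes Igfbp7 (at least 2376-fold), Aplnr (at least 481-fold) and Adgrl4 (at least 469.7-fold), each with 0 reads. Aqp1, a water channel of vessels, had 1 read against 11080, a ratio of 6265 (1124 to 2.47e+05). Macrophage markers fell in 13 of 16 cases (14), with a median of -7.82, or -7.74 with bounds (adjusted p = 0.0775 with an estimated correlation), while 1 of them, Cd68, rose by 4.73 (adjusted p = 0.0358). Myod1 rose by 5.66 and Sdc4, a syndecan, by 2.62, and 5 of 10 satellite cell genes fell, among them Heyl by 5.84. Pericyte markers fell in 9 of 11 cases (median -5.30; adjusted p = 0.170 with an estimated correlation), tendon markers in 7 of 8 (median -5.21; adjusted p = 0.134 with an estimated correlation) and Schwann cell genes in 9 of 10 (median -5.03; adjusted p = 0.126 with an estimated correlation). Lymphocyte markers fell in 3 of 6 cases (median -5.01, or -3.30 with bounds; adjusted p = 0.200 with an estimated correlation), a count of 1 without whole muscle 2 or 3. The Cd68 call was lost without single fiber 1 or 3 or any whole muscle library, and without any whole muscle library 1 satellite cell gene rose and 3 fell.

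edgeR called 4716 of 14028 genes in single fibers against whole muscle, 1945 higher and 2771 lower, with 6332 at an unadjusted p under 0.05 and 0 of the higher genes within the background density. The groups did not overlap in 4588 of these genes, where chance gives a share of 10% for 3 libraries against 3 among genes not selected by a test, and 395 had a group at 0. The count was 7617 without single fiber 2 and 1753, 1540 and 1637 without whole muscle 1, 2 and 3. Without these same 3 libraries in turn, 12, 13 and 13 immediate early genes, 4, 4 and 6 stress genes, 2, 2 and 3 fast sarcomere genes, 4, 3 and 3 mitochondrial mRNAs, 1, 1 and 2 glycolysis genes, 1, 0 and 1 respiratory chain genes, 0, 0 and 1 junction genes and 2, 1 and 3 denervation genes rose. In the same order 8, 8 and 8 fibroblast markers, 4, 4 and 3 tendon markers and 3, 3 and 3 fatty acid genes fell, and Rrad, Sox9, Sgms2 and Dusp2 lost their calls (adjusted p = 0.0539 to 0.0658). The denervation list gave 7 higher without single fiber 1, the junction list 4 without single fiber 3, and the glycolysis list 10 without single fiber 2.

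Pools of 5 fibers against whole muscle shared the rise of immediate early and stress genes. Of 31 immediate early genes 28 rose (30 adjusted over the list alone), with a median of 3.49 (camera adjusted p = 4.91e-32; adjusted p = 0.0209 with an estimated correlation), Fosb to 185 ± 51.8 CPM (n = 3) against 0.167 and Egr1 to 1139 ± 55.4. Of 17 stress genes 14 rose (15), with a median of 2.63 (camera adjusted p = 1.41e-13; adjusted p = 0.0209 with an estimated correlation), Hspa1a by 9.22 to 654 ± 647 CPM. Mitochondrial mRNAs rose in 7 of 13 cases (11), with a median of 3.01 (camera adjusted p = 2.57e-11; adjusted p = 0.254 with an estimated correlation), and ribosomal protein genes in 27 of 57 (44), with a median of 1.56 (camera adjusted p = 8.04e-25; adjusted p = 0.254 with an estimated correlation). Fibroblast markers fell in 8 of 16 cases (14), with a median of -3.27 (camera adjusted p = 8.44e-09; adjusted p = 0.319 with an estimated correlation), and adipocyte markers in 7 of 8 (7), with a median of -7.64 (adjusted p = 0.254 with an estimated correlation). Macrophage markers fell in 5 of 16 cases (12), with a median of -3.60 (adjusted p = 0.260 with an estimated correlation), Lyz2 by 6.15. Of the 16 endothelial markers 0 passed, with a median of -0.56 (camera adjusted p = 0.0441; adjusted p = 0.726 with an estimated correlation), Fabp4 at -2.27 (adjusted p = 0.0559) and Gpihbp1 at -0.95. The pericyte gene Rgs5 (-0.17) and the globin Hbb-bs (-1.23) did not pass either.

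The endothelial list stood at 116% and 87.2% of whole muscle in 5-fiber pools 1 and 2 and at 7.17% in pool 3, and its median was 0.01 without pool 3. Pools 1 and 2 were also those with 58.0% and 68.8% of the receptor-family genes read and with 38.3% (38.29% to 38.33%) and 34.2% (34.13% to 34.19%) of reads on mitochondrial ribosomal RNA. Outside the lists the largest rises were Eid3 (9.30), the chemokine Cxcl10 (103-fold), Lonrf3 (74.6-fold) and Midn (73.3-fold). The largest falls were Retnla, with 1 read (a ratio of 2284, 409.7 to 9.02e+04), Hp (484-fold), Cyp2e1 (162-fold) and the cysteine dioxygenase Cdo1 (134-fold). edgeR called 1307 of 14764 genes, 684 higher and 623 lower, with 3952 at an unadjusted p under 0.05, 4 of the higher genes within the background density and 1306 without overlap. RLE factors gave 906 higher and 518 lower, so 63.6% of the called genes were higher against 52.3%, and moved the median of all genes from -0.03 to 0.13. The signs of the glycolysis (median -0.04, mean 0.18) and satellite cell medians (-0.06, mean 0.03) flipped under RLE and upper-quartile factors.

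Pools 1 and 3 and each whole muscle library decided much of the number of calls in the 5-fiber comparison. The count of called genes was 202 without pool 1, 1056 without pool 2, 7920 without pool 3 and 7, 46 and 45 without whole muscle 1, 2 and 3. In that last order 2, 6 and 7 immediate early genes, 0, 1 and 1 stress genes, and 0 ribosomal protein genes and mitochondrial mRNAs rose. Fibroblast and macrophage markers gave 0 lower each time, and adipocyte markers 0, 4 and 4. The calls were lost while the medians kept their direction. In the same order the immediate early median was 3.47, 3.43 and 3.67, and the adipocyte median -7.61, -7.79 and -7.54. Without pool 1, 3 stress genes, 3 ribosomal protein genes and 0 mitochondrial mRNAs rose, and 0 fibroblast and 2 macrophage markers fell. Without pool 2, 5 fibroblast markers fell. Without pool 3, 46 ribosomal protein genes and 12 mitochondrial mRNAs rose, and 16 fibroblast and 13 macrophage markers fell. Eid3, Cxcl10, Lonrf3 and Midn lost their calls without any whole muscle library (adjusted p = 0.0527 to 0.128), and Hp without whole muscle 1 (0.0527). With the single pool that had under 50% of receptor-family genes read, a choice made after seeing the data in which that pool was assumed to vary like whole muscle, 7422 genes were called.

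Pools of 20 fibers against whole muscle repeated the rise of immediate early genes, 26 of 30 with 0 lower (26 adjusted over the list alone) and a median of 3.04 (camera adjusted p = 2.99e-06; adjusted p = 0.678 with an estimated correlation). Fosb rose by 9.09 (SE 0.75), Fos by 6.11, Egr1 by 5.50 and Ankrd1 by 4.12. Of 17 stress genes 8 rose (8), with a median of 0.99 (camera adjusted p = 0.180; adjusted p = 0.944 with an estimated correlation), Hspa1a by 7.31. Slow sarcomere genes fell in 10 of 12 cases (10), with a median of -3.57 (camera adjusted p = 3.07e-06; adjusted p = 0.386 with an estimated correlation), and fatty acid genes in 12 of 20 (13), with a median of -1.53 (camera adjusted p = 8.49e-06; adjusted p = 0.594 with an estimated correlation), Acadvl by 5.33. All 16 fibroblast markers fell (16), with a median of -3.48 (camera adjusted p = 2.35e-08; adjusted p = 0.436 with an estimated correlation), as did 7 of 8 adipocyte (7, median -4.80) and 12 of 16 macrophage markers (12, median -2.42), both at an adjusted p = 0.436 with an estimated correlation. Endothelial markers fell in 6 of 16 cases (4), with a median of -1.27 (camera adjusted p = 6.08e-04; adjusted p = 0.678 with an estimated correlation), Fabp4 by 2.62. They stood at 15.1% and 18.1% of whole muscle in pools 1 and 2 and at 73.1% in pool 3, and 13 fell without pool 3, 11 without whole muscle 1 and 3 without whole muscle 3. The fast sarcomere list stood at 104%, 15.7% and 84.1% in pools 1 to 3. In pool 2 the endothelial percentage was thus no lower than that of the fibers' own genes. The B cell receptor gene Cd79b rose by 4.64 and was the only lymphocyte marker of 7 called, in a list with a median of -0.00 and a mean of 0.79, whose sign flipped under RLE and upper-quartile factors.

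Ribosomal protein genes gave 8 higher of 57 in the pools of 20 (0 adjusted over the list alone), with a median of 0.90 (camera adjusted p = 0.936). Without 20-fiber pool 2, the library with 20.9% of its reads on Gm10800 (20.85% to 20.93%), 44 rose. Their number was 3 and 4 without pools 1 and 3 and 0, 1 and 1 without whole muscle 1, 2 and 3. Respiratory chain genes gave 6 lower of 36 (1), with a median of -0.78 (camera adjusted p = 1.45e-04; adjusted p = 0.830 with an estimated correlation). This number was 10 without pool 1, 20 without pool 2 and 2 without whole muscle 2 or 3, and that of the fatty acid genes 6 without whole muscle 2. The 30 fast sarcomere genes had a median of -0.29 (camera adjusted p = 0.0175; adjusted p = 0.921 with an estimated correlation), with 1 higher and 3 lower (0 and 1), Ryr1 at 2.80 and Myh2 at -3.15. Without pool 2 these numbers were 6 and 10, without pool 1 or whole muscle 1 they were 0 and 3, without whole muscle 2 0 and 2, and without whole muscle 3 0 and 1. Background subtraction, chosen after seeing the data, turned the median to 0.15 (adjusted p = 0.697). Among the largest rises outside the lists, Muc16 (at least 374-fold), Fam135b (ratio 1092, 195 to 4.32e+04) and Dnah8 (ratio 816, 145.5 to 3.23e+04) lay within the background density of these pools. The largest falls were Hp (55.0-fold), the myosin-binding protein Mybph (52.3-fold), Retnla (47.8-fold) and Mfap4 (39.8-fold). edgeR called 7446 of 16969 genes, 5147 higher and 2299 lower, with 8710 at an unadjusted p under 0.05, 7228 without overlap and 1128 with a group at 0. Of the higher genes 3318 lay within the background density, and of 343 receptor-family genes tested 340 were higher. Upper-quartile factors moved the median of all genes from 0.38 to 0.66, and the count was 13512 without pool 1, 12607 without whole muscle 1 and 4538 with background reads subtracted, a choice made after seeing the data.

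Comparisons between the fiber groups ask what the number of fibers in a library changes. Single fibers differed from pools of 5 in 2 called genes, both lower: Ctla2a, a cathepsin inhibitor, and the globin Hba-a2, which was named after its values were seen. Hba-a2, with 87.3% of its windows shared with another locus, was at 0.0340 ± 0.0318 CPM against 29.95 ± 15.1 (n = 3), with 2 reads in single fibers (log2 ratio -9.57, counting interval -12.61 to -7.71; adjusted p = 0.0371). Ctla2a had 1 read against 3611, a ratio of 4269 (766 to 1.69e+05; adjusted p = 0.0436). The 15 endothelial markers tested had a median of -7.87, or -7.47 with bounds, and 0 passed over all genes but 15 adjusted over the list alone (camera adjusted p = 2.53e-09; adjusted p = 0.397 with an estimated correlation). The 5 erythroid genes had a median of -9.26 (camera adjusted p = 4.06e-07; adjusted p = 0.191 with an estimated correlation). Immediate early genes had 0 calls over all genes and 8 lower adjusted over the list alone, with a median of -0.71 (camera adjusted p = 7.03e-09; adjusted p = 0.191 with an estimated correlation). Of 12700 genes 1132 had an unadjusted p under 0.05, and DESeq2 called 423 and limma voom 1173. The count was 833 without 5-fiber pool 3, with 15 endothelial, 6 pericyte, 4 erythroid, 6 stress and 5 immediate early genes lower, and 0 without any other one of the 6 libraries.

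Markers of other cell types were lower in single fibers than in pools of 20. With the replicate number as a block, 7 of all the calls in this comparison remained, so most of the marker calls below ended. Of 16 endothelial markers 15 were lower in single fibers (16 adjusted over the list alone), with a median of -6.97 (camera adjusted p = 1.98e-06; adjusted p = 0.484 with an estimated correlation), Fabp4 by 9.32 (0.171 against 101 CPM). Pericyte markers were lower in 8 of 10 cases (median -4.84; adjusted p = 0.484 with an estimated correlation) and in 5 without 20-fiber pool 2, with Rgs5 at -7.55. Erythroid genes were lower in 4 of 6 cases (median -8.09; adjusted p = 0.484 with an estimated correlation), with Hbb-bs at 3 against 4621 reads. Schwann cell genes were lower in 6 of 9 cases (median -4.69, or -4.63 with bounds; adjusted p = 0.484 with an estimated correlation). Macrophage markers were lower in 6 of 10 cases and higher in 1 (median -4.78; adjusted p = 0.484 with an estimated correlation), and in 11, 10 and 10 cases without single fibers 1, 2 and 3. Both lists stood low in 20-fiber pools 1 to 3, with medians of 1.48, 2.50 and 1.13 CPM for Schwann cell genes. Macrophage markers stood at 0.854, 1.97 and 3.83 CPM there. With background reads subtracted, chosen after seeing the data, 7 list calls of this comparison ended. Fibroblast markers were lower in 3 of 15 cases (median -2.21; adjusted p = 0.595 with an estimated correlation), in 15 without single fiber 1, in 13 without 20-fiber pool 1 and in 1 without pool 2. Outside the lists the largest falls were Apold1 (at least 1025-fold), Timp4 (at least 415-fold), Aqp1 (ratio 2166, 388 to 8.56e+04), Adgrf5 (2103, 377 to 8.31e+04), Cd93 (1974, 354 to 7.8e+04), Ctla2a (1549.9, 278 to 6.13e+04), Itga6 (449.6, 124 to 3719) and Cacna1e (273, 75.3 to 2265).

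Higher in single fibers than in pools of 20 were Srxn1, the sulfiredoxin that restores oxidized peroxiredoxins (1140.4 ± 995 CPM against 14.2, log2 fold change 6.33, SE 1.18, adjusted p = 0.00611), the metallothionein Mt3 (5.73), Mustn1 (3256 ± 2671 CPM against 86.3), Pdpn, Mpc1, a subunit of the mitochondrial pyruvate carrier, Tnfrsf12a, Aimp2 and Tmem140. Respiratory chain genes were higher in 8 of 36 cases (4 adjusted over the list alone), with a median of 1.501 (camera adjusted p = 5.92e-10; adjusted p = 0.484 with an estimated correlation). Ribosomal protein genes were higher in 8 of 57 cases (3), with a median of 1.24 (camera adjusted p = 1.39e-13; adjusted p = 0.484 with an estimated correlation), and fast sarcomere genes in 3 of 30, with a median of 1.44 (camera adjusted p = 7.33e-08; adjusted p = 0.484 with an estimated correlation). The respiratory chain number was 3 without single fiber 2, 5 without single fiber 3 and 4 without 20-fiber pool 2, and the ribosomal one 3, 4 and 3 without single fibers 1, 2 and 3. Of 31 immediate early genes 5 were higher and 7 lower, with a median of -0.18 and a camera direction of up (adjusted p = 0.154): Btg2 was higher by 2.71 and Fosb stood at -2.09. The number higher was 3 without 20-fiber pool 2, and the number lower 4, 3 and 4 without single fibers 1, 2 and 3 and 4 without 20-fiber pool 3. edgeR called 6123 of 16978 genes, 1446 higher and 4677 lower, with 8010 at an unadjusted p under 0.05, 5953 without overlap and 1112 with a group at 0. In 3546 of the lower genes the pools lay within the background density, and 370 of 400 receptor-family genes tested were lower. The median of all genes was -0.74 with TMM and -0.96 with upper-quartile factors. The count was 10367, 9849, 10714 and 3931 without single fiber 1, single fiber 3, 20-fiber pool 1 and 20-fiber pool 2, and 1542 with background reads subtracted, chosen after seeing the data. With the replicate number as a block it was 7, with 0 higher, so the calls of the genes named above as higher in single fibers were lost.

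Between pools of 5 and pools of 20 edgeR called 0 of 17113 genes, with 1502 at an unadjusted p under 0.05, while DESeq2 called 179 and limma voom 760. Immediate early genes had a median of 1.25 and 5 higher in pools of 5 adjusted over the list alone, stress genes a median of 1.98, respiratory chain genes 1.53 and Schwann cell genes -1.65, all at adjusted p = 0.546 or more with an estimated correlation. The count was 49 without 5-fiber pool 2 and 86 without 5-fiber pool 3, and the median of all genes moved from -0.08 to -0.46 with upper-quartile factors.

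**Figure D3:**
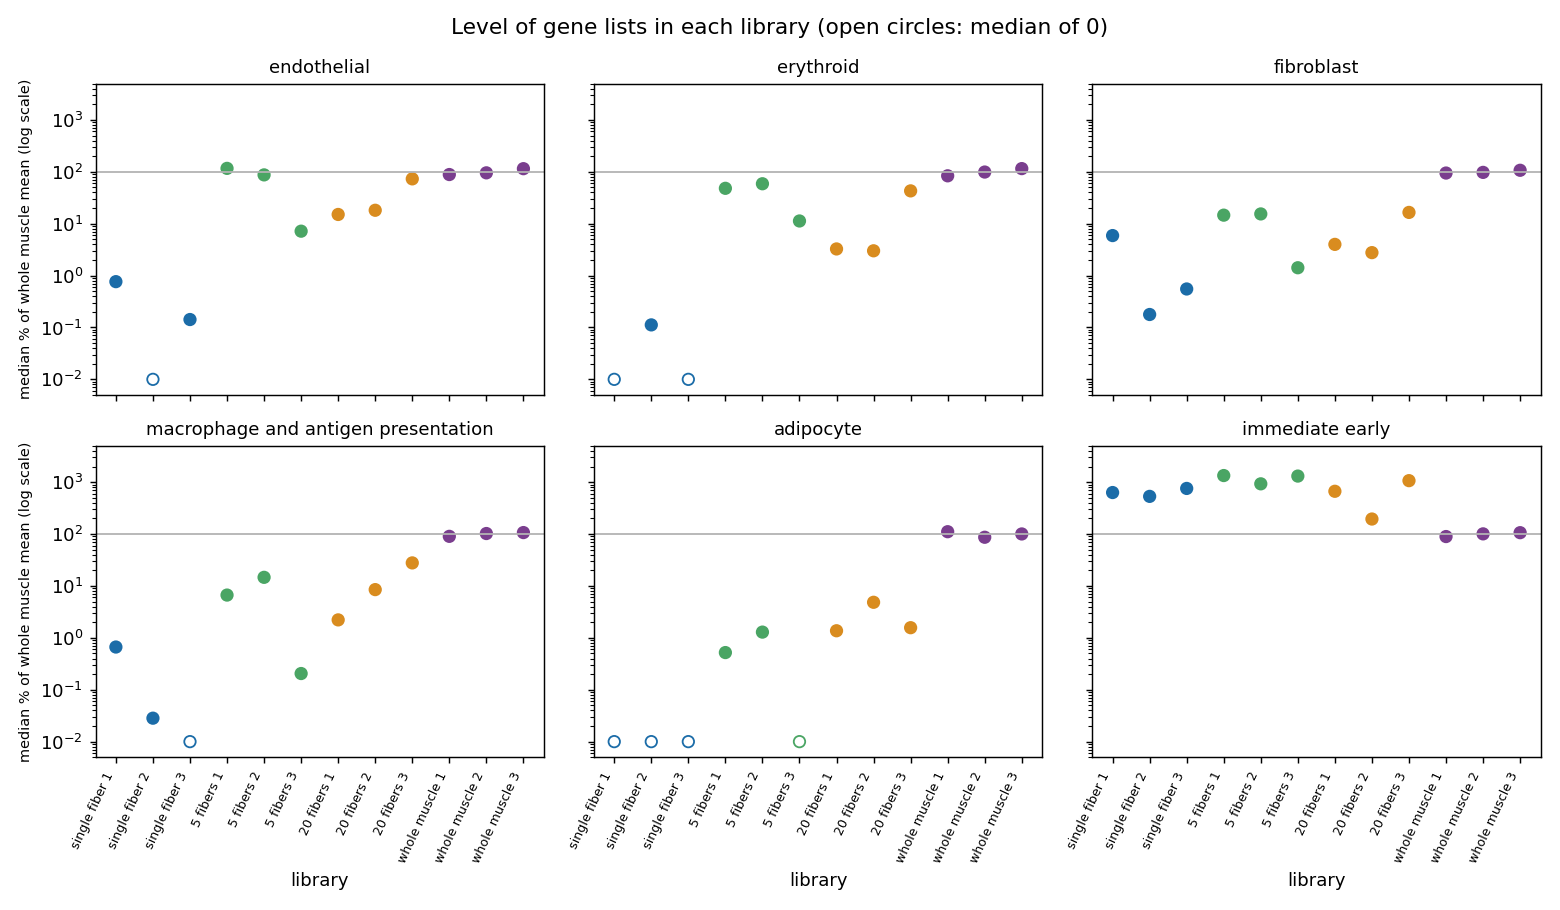
Each panel gives for 1 list the median over its members of the level in a library as a percentage of the whole muscle mean, on a log scale, for the 12 libraries, with open circles for a median of 0. Endothelial markers stand between 0 and 0.763% in single fibers and between 7.17% and 116% in the pools, while the immediate early list stands at 195% or more in all 9 fiber libraries.

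Genes called against whole muscle were shared between the 3 fiber groups. In the same direction in all 3 comparisons, 347 genes were higher, where independent calls would give 13.7, and 390 were lower, where they would give 21.2. In 20 simulations of unchanged groups set against the same whole muscle libraries the number was 0, but such groups gave almost no calls. The 3 comparisons share these libraries, from which part of the excess may come. The pools of 5 limit these numbers: without whole muscle 1, 2 or 3 they held 7, 46 and 45 calls in all, and 202 without 5-fiber pool 1, so no more could be shared. Higher in all 3 were 21 immediate early genes, 8 stress genes, 8 ribosomal protein genes, 3 mitochondrial mRNAs and 3 denervation genes, but without whole muscle 1 at most 2 immediate early genes and 0 of the others could be. Lower in all 3 were 8 fibroblast, 7 adipocyte, 5 macrophage, 3 tendon and 3 Schwann cell markers and 3 slow sarcomere genes, but 0 endothelial markers.

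Myosin heavy chain reads, which mark fiber types, came mostly from Myh4, the type IIb gene. Of the reads on Myh1, Myh2, Myh4 and Myh7, Myh4 took 98.1% ± 2.11 (SD, n = 3) in single fibers, 91.7% ± 6.27 in pools of 5, 97.4% ± 0.972 in pools of 20 and 89.5% ± 0.203 in whole muscle. The share was 8.57 points higher in single fibers and 7.84 points higher in pools of 20 than in whole muscle (exact two-sided permutation p = 0.1 for each, the smallest that 3 against 3 libraries can give; 0.185 adjusted over 24 comparisons) and 2.19 points higher in pools of 5 (exact p = 0.4). Myh2, the type IIa gene, took 2.97% ± 0.139 of these reads in whole muscle and 0.628% ± 0.141, 1.47% ± 0.980 and 0.356% ± 0.164 in single fibers, pools of 5 and pools of 20, and Myh7, the slow gene, 0.628% ± 0.221 in whole muscle against 0.000107%, 0.0212% and 0.0714% (exact permutation p = 0.1 in each case). Single fiber 2 differed from the other single fibers in Myh1, the type IIx gene, with a share of 3.55% (Clopper-Pearson 95% interval 3.50% to 3.61%). Myh7 had 0 reads in single fibers 2 and 3 and in 5-fiber pool 3. A limit of 3 counts allows shares of up to 0.000687%, 0.00156% and 0.00124% there. The Clopper-Pearson upper bounds were 0.000845%, 0.00192% and 0.00153%. Of the sampled windows of Myh1, Myh2 and Myh7, 27.9%, 22.3% and 20.3% were shared with another locus.

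**Figure D4:**
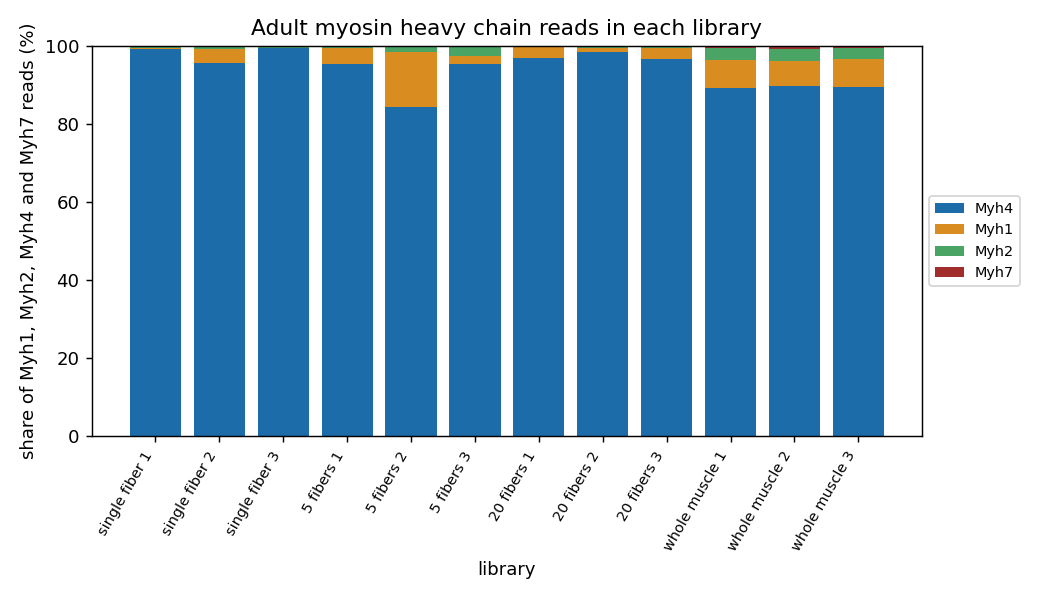
Each bar splits the reads on Myh1, Myh2, Myh4 and Myh7 in a library into the 4 genes, in percent. Myh4 takes 84.5% in 5-fiber pool 2, from 89.3% to 89.7% in whole muscle and from 95.3% to 99.4% in the other 8 libraries.

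The number of genes detected after thinning to 4702823 reads was 15611 ± 1974 in single fibers, 22751 ± 7575 in pools of 5, 38781 ± 8733 in pools of 20 and 18142 ± 137 in whole muscle (SD, n = 3). Exact two-sided permutation tests of single fibers and of pools of 20 against whole muscle gave p = 0.1 each, the smallest possible (0.15 adjusted over 6), and pools of 5 against whole muscle p = 0.4. With background reads subtracted, chosen after seeing the data, the pools of 20 had 25004 detected genes, against 17604 in whole muscle. The median SD of log2 CPM between replicates, over 6526 genes, was 0.54 in single fibers, 0.64 in pools of 5, 0.48 in pools of 20 and 0.18 in whole muscle. It was 0.35 in single fibers without single fiber 2, 0.25 in pools of 5 without pool 3 and 0.27 in pools of 20 without pool 2. The order of single fibers and pools of 20 depended on the minimum level. At a mean of 1 CPM or more the values were 0.51 and 0.81, and at 100 CPM or more 0.47 and 0.72. Across the 6526 genes, which are not independent replicates, Spearman's rho was 0.924 between single fibers 1 and 3. It was 0.787 and 0.785 between each of them and single fiber 2. In whole muscle it ranged from 0.958 to 0.973.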

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

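The tests of expression by myofibers themselves and of scaling were chosen only after the result was seen, as were the alternatives with background reads subtracted; the other tests were written down before their values were seen.

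Receptor-family genes, which muscle is not known to express, held more RPM in 7 fiber libraries than the 21.9 in the highest whole muscle library. The values were 69.0 and 22.0 in single fibers 1 and 3, 188.5 and 579 in 5-fiber pools 1 and 2, and 1019, 8905 and 1790.2 in 20-fiber pools 1 to 3. Expression of receptor genes by the fibers would put most reads on few genes, but the 151 genes with the most held 18.1% of their summed read density in pools of 20, against 93.7% in the same share of other protein-coding genes and 13.6% for simulated even coverage. In pools 1, 2 and 3 alone it was 31.4%, 19.4% and 23.2%. It was 43.7% and 37.6% in 5-fiber pools 1 and 2 and 75.4% and 100% in single fibers 1 and 3. Pool 2, with 8905 RPM, weighed most in the 18.1%. In 20-fiber pool 1 and in these 5-fiber and single fiber libraries receptor expression was not excluded, and the share cannot decide it. These libraries held fewer such reads than 20-fiber pools 2 and 3, and even coverage was simulated for the summed pools of 20 only. In single fiber 3 the 100% was fixed in advance, since 147 receptor genes had a read, fewer than the 151. Genomic DNA in the lysates is a candidate explanation: all 12 libraries held reads of the Y-linked gene Ddx3y, and DNA of a male carries 1 X. Among genes without a read in whole muscle the ratio of X-linked to autosomal median read density was 0.335, 0.523 and 0.548 in pools of 20. The bootstrap 95% intervals, 0 to 0.531, 0.473 to 0.580 and 0.404 to 0.624, allow for DNA. In 5-fiber pools 1 and 2 the X-linked median was 0, and so was the ratio (upper bounds 0.118 and 0.384). Single fibers had no ratio, as both medians were 0. With reads pooled over genes it was 0.451 and 0.437 in 5-fiber pools 1 and 2. It was 0.284 and 0.215 in single fibers 1 and 3, and 0.583, 0.554 and 0.563 in pools of 20. The DNA reading thus rests on the pools of 20. No biological explanation beyond receptor expression was tested, and single fiber 3 lay close to whole muscle.

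Effects against whole muscle differed between single fibers and pools of 20 for several cell types, by the direct comparison of these groups with a preset correlation, but all 5 calls below were lost with an estimated one (adjusted p = 0.484 for each). The median log2 difference was -6.97 for endothelial, -4.84 for pericyte and smooth muscle, -4.78 for macrophage, -8.09 for erythroid and -4.63 (with bounds) for Schwann cell and nerve genes. Background reads in the pools do not account for the endothelial part, since after their subtraction the median was -7.91 (bootstrap 95% interval -9.11 to -4.64), or -6.76 with the 4 of 15 markers at 0 set to their bounds. The pericyte, macrophage, erythroid and Schwann cell lists were not weighed against background here. Whether some fibers express these genes themselves stays open, since the value at hand, the difference of -6.97 (-8.26 to -4.25), is the pattern itself and cannot test it. Endothelial cells carried along with some fibers may be the source: after subtraction 15 of the 16 markers lay within 2 log2 units of the list's median in pools of 20 against whole muscle. Of the abundant markers Fabp4, which adipocytes also express, stood at 101 CPM in pools of 20, and the labels name no sort or gate that would remove such cells.

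The rise of immediate early genes in fibers over whole muscle was weighed as the third pattern. Scaling, or dilution of fiber RNA by the RNA of other cells in whole muscle, is argued against as the whole cause: relative to the fast sarcomere list the median rise in single fibers was 1.88 (bootstrap 95% interval 1.10 to 3.32). Background reads are argued against as well, with a median of 3.38 (2.51 to 3.87) in pools of 20 after their subtraction. With 3 libraries in a group, these bootstrap intervals are no measure of the spread between replicates. The immediate early list's own call in these 2 groups did not hold with an estimated correlation. A response of the fibers to their isolation stays open as a hypothesis. Isolation and the way the RNA was obtained went together in single fibers, the labels do not say how RNA of the pools was obtained, and neither was tested.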

How the results depend on the processing

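Background subtraction, the protein-coding fit and the fits without libraries of over 50% receptor-family genes read were chosen only after the data were seen; the other alternatives were fixed before. Of the named genes, the call stayed the same in 2566 results under alternatives fixed before and 357 under later ones, was lost in 146 and 13 and gained in 72 and 28, and none reversed. In the model of 2 groups 25 of the calls of named genes in isolated fibers ended, among them Myl3, Fabp4, Rgs5 and Hbb-bs, and 79 results stayed the same. With the replicate block 15 ended: Ctla2a (single fibers against pools of 5), mt-Nd6 and S100a8 (isolated fibers), all 8 named genes higher in single fibers than in pools of 20, such as Srxn1 and Mt3, and Apold1, Timp4, Itga6 and Cacna1e, lower there. The cause was not tested for any of these, nor for the values below unless one is given. With an estimated correlation the list calls that held were slow sarcomere and Schwann cell and nerve (isolated fibers) and immediate early and heat shock (pools of 5 against whole muscle). With fry 2, 3, 2, 7, 12, 10 and 13 list calls ended in isolated fibers, single fibers, pools of 5 and pools of 20 against whole muscle, single fibers against pools of 5, single fibers against pools of 20, and pools of 5 against pools of 20. With background subtracted these numbers were 1, 0, 1, 2, 0, 7 and 7. A list reversed in 3 cases: endothelial markers in pools of 5 against whole muscle without 5-fiber pool 3 (median 0.012, adjusted p = 0.882; -1.03 without pool 1), and with background subtracted fast sarcomere (0.15, 0.697) and glycolysis genes (0.24, 0.853) in pools of 20 against whole muscle.

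Counts of called genes moved over 1.5 times as follows. For isolated fibers DESeq2 gave 6411, limma voom 14352 and the model of 2 groups 596, and leaving out a library gave 1193 to 7271. Single fibers against whole muscle gave 2858 with a mean of 5 CPM or more (fewer genes tested), 3132 with the replicate block, 2854 with all 12 libraries and 1540 to 7617 without a library. Pools of 5 against whole muscle gave 3094 with DESeq2, 7194 with limma voom, 2535 without a low-count filter, 231 with the block, 7422 without the 2 pools of high background and 7 to 7920 without a library. Pools of 20 against whole muscle gave 23388 without a filter, 4312 with a mean of 5 CPM, 4806 when thinned, 4538 with background subtracted and 6605 to 13512 without a library. Single fibers against pools of 5 gave 423 with DESeq2, 1173 with limma voom, 768 without a filter, 1 with a mean of 5 CPM, 1 when thinned, 0 with the block, 755 with all 12 libraries, 8 for protein-coding genes, 1 without the 2 pools of high background and 0 to 833 without a library. Single fibers against pools of 20 gave 15348 without a filter, 1949 with a mean of 5 CPM, 2990 when thinned, 7 with the block, 1542 with background subtracted and 3931 to 10714 without a library. Pools of 5 against pools of 20 gave 179 with DESeq2, 760 with limma voom, 6 without a filter, 1 with the block and 0 to 86 without a library. The replicate numbers did not pair the libraries: the correlation of libraries with the same number ranged from -0.37 to 0.45, and in no comparison did all 3 correlate best with their own number.

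Detected genes with 10 or more reads were 8618, 9492, 18031 and 11679 in single fibers, pools of 5, pools of 20 and whole muscle, and at 1 CPM or more without thinning 10153, 11992, 23708 and 13111. Without thinning they were 19308 in single fibers and 20889 in whole muscle. With background subtracted they were 25004 in pools of 20 and 17604 in whole muscle, and with 10 or more reads as well 8123, 8473.3, 11502 and 11214. Leaving out a library gave 14634 to 16608, 19022 to 26594, 33994 to 42546 and 18068 to 18204. The spread in single fibers and pools of 20 was 0.51 and 0.81 at a mean of 1 CPM or more, and 0.47 and 0.72 at 100 CPM or more. At the minimum of 10 CPM, leaving out a library gave 0.35 to 0.51 in single fibers and 0.25 to 0.70 in pools of 5. It gave 0.27 to 0.49 in pools of 20 and 0.13 to 0.17 in whole muscle. The Myh4 share of whole muscle was 88.3% with 9 myosin genes as denominator, and the calls shared by all 3 comparisons with whole muscle, 737, were 1386 with DESeq2 and could be at most 7, 46 and 45 without whole muscle 1, 2 and 3.

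Other splits of the libraries gave as many genes as the real one in 2 of 100 cases for isolated fibers, the real one included, a share under 0.05. The real one called 3370 genes and the highest other split 4233. Most other splits mixed whole muscle with fiber libraries and called 0 genes. The test therefore speaks against an arbitrary split, but such a count was not particular to fibers against whole muscle. The split with 4233 set 5-fiber pool 1 and 20-fiber pools 2 and 3 against the rest, and its cause was not tested. For pairs of groups 10 splits are too few for a share under 0.05. The real one was 1 of 10 for single fibers (4716), pools of 5 (1307) and pools of 20 (7446) against whole muscle and single fibers against pools of 20 (6123), each with at most 0 in another split. It was 2 of 10 for single fibers against pools of 5 (2, at most 2) and 10 of 10 for pools of 5 against pools of 20 (0, at most 0).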

Other observations

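The comparisons in this part were chosen only after the values were seen. The genes in it that the rule for names did not take (Runx1, Acadm, Ndufa4 and Flt1) were picked from those values. Single fiber 2 differed from single fibers 1 and 3 in several lists. All 36 respiratory chain genes were higher in it than in both others, with a median difference of 1.70 on the log2 scale, as were 19 of 20 fatty acid genes (1.64) and 12 of 13 mitochondrial mRNAs (1.89). Glycolysis genes went the same way, 13 of 20 higher than both and 0 lower (0.48), and fast sarcomere genes were higher in 14 of 30 cases and lower in 3 (0.23), while slow sarcomere genes were mixed (5 higher and 4 lower of 12, 0.13). Ndufa4, a respiratory chain subunit, stood at 2926 CPM against 513 and 443, Acadm, a fatty acid dehydrogenase, at 338 against 57.2 and 56.2, and the type IIx myosin Myh1 at 1006 against 49.0 and 16.1. Some genes, picked for this, were lower in it. Ankrd1 stood at 213 CPM against 8179 and 4774, Rrad at 18.8 against 1615 and 1105, Myod1 at 21.4 against 627 and 1018, Runx1, a transcription factor of denervated muscle, at 8.18 against 215 and 304, and the lysosomal gene Cd68 at 1.49 against 244 and 266. Of 31 immediate early genes 19 were lower in single fiber 2 than in both others (median -0.73), and 13 of 20 denervation genes (-0.52), but heat shock and metal stress genes were not lower as a list (8 higher and 8 lower of 17, 0.07). Of 16 fibroblast markers 10 were lower and 0 higher (-1.90). These are values of 1 library, with no test.

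Libraries of unlike fiber number could lie closer than replicates. Across genes with a mean of 10 CPM or more, without thinning, Spearman's rho was 0.94 between single fiber 2 and 5-fiber pool 3. It was 0.789 and 0.786 between single fiber 2 and the other single fibers. Single fiber 2 and 5-fiber pool 3 had the highest totals of all libraries (27787120 and 24719718 reads). Among fiber libraries they also had the smallest shares of receptor-family genes read (4.73% and 4.397%). Whether depth and background account for their likeness was not tested. In 5-fiber pools 1 and 2 the endothelial receptor gene Flt1 stood at 104 and 88.3 CPM, above the 14.1 to 19.1 of whole muscle. In pool 3 it stood at 5.60. Flt1 does not speak for its list, whose median was 116% and 87.2% of whole muscle in pools 1 and 2. Hspa1a stood at 644, 1331 and 46.2 CPM in the pools of 5.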
